A study of Homo sapiens with 24 samples.

How the data were processed

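RNA was sequenced from 24 libraries of the human lines UCSD-AML1, UT-7 and TF-1, each given 3 mM cyclocreatine or vehicle for 24 h, with 4 libraries per group and 6 groups. Per the labels, RNA was extracted with RNeasy columns and sequenced on an Illumina HiSeq. The deposited files hold raw counts, whole numbers per RefSeq gene symbol for 25728 symbols, in 1 file per library. The submitters' processing notes name FastQC, TopHat2, RSEM and the builds GRCh37 and hg19, and their versions, order and roles are not given in the sources used here. The counts were checked for their unit: totals differed between libraries, and near-identical genes such as SMN1, SMN2 and EIF3CL stood at 0 counts over all libraries, as when only uniquely placed reads are counted. Levels of genes with near-identical copies are therefore uncertain, and so are those of overlapping and antisense genes, since strand use is not given in the sources used here. Replicates were not pooled, and each library was assigned to its group from its labels.

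Library totals ran from 12794998 to 21200662 counts. They were 15112620 to 17047051 in TF-1 vehicle, 14993466 to 21200662 in TF-1 cyclocreatine, 12874459 to 15115540 in UT-7 vehicle, 12794998 to 13891082 in UT-7 cyclocreatine, 14297926 to 17414130 in UCSD-AML1 vehicle and 14297101 to 15818426 in UCSD-AML1 cyclocreatine. Between 16086 and 17102 genes had a count in a library. A count of 0 was read as allowing up to 3 counts per library, which covers counting error only. Counts of replicate pairs differed by more than counting error in all 36 pairs of a group (chi-square per degree of freedom 1.29 to 19.3 over genes with a summed count of at least 20), so no library was a copy of another.

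Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr with the groups (smallest count 10, smallest total 15), which left 14588 genes holding at least 99.93% of the counts of each library, and libraries were scaled by TMM. All libraries entered 1 group-means model with robust quasi-likelihood dispersions (18 residual degrees of freedom before moderation, median biological coefficient of variation 0.0578). The 7 contrasts were the effect of cyclocreatine in each line, the mean of the 3 effects, and the 3 differences between lines in that effect. Tests looked at both directions, and genes with a Benjamini-Hochberg adjusted p under 0.05 within a contrast were called. CPM used TMM-scaled totals, and log2 CPM a prior count of 2. Principal components were computed per line. The overlap of calls was set beside the number that independent calls would give.

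Gene lists were tested with camera (inter-gene correlation preset to 0.01) within each contrast, with Benjamini-Hochberg adjustment over the 35 lists that had at least 3 measured members, of 36 fixed. They were creatine pathway; osmolyte transport; arginine, proline and polyamine metabolism; cholesterol biosynthesis; fatty acid synthesis and LXR targets; amino acid and integrated stress response; serine and one-carbon metabolism; glycolysis; hypoxia response; nuclear-encoded oxidative phosphorylation; mitochondrial-encoded transcripts; tricarboxylic acid cycle. Mitochondrial biogenesis and chaperones, energy stress with FOXO and MondoA targets, autophagy and lysosome, p53 targets, BCL2 family, G1/S and DNA replication, G2/M and mitosis, MYC and ribosome biogenesis, and cytosolic ribosomal proteins were further lists. The rest were endoplasmic reticulum unfolded protein response, heat shock, NRF2 targets, metallothioneins and zinc response, JAK-STAT targets, MAPK feedback and immediate early genes, NF-kB and inflammatory genes, type I interferon response, stem and progenitor regulators, erythroid, megakaryocyte, granulocyte and monocyte, lymphoid, and stromal and epithelial markers, and replication-dependent histones.

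Baseline levels of the creatine genes and MECOM were compared between the vehicle groups of the lines with an exact permutation test on log2(CPM + 0.1), over 70 arrangements of 4 against 4 libraries and in both directions, adjusted over 27 tests (Python 3.11.15, numpy 2.4.6, scipy 1.17.1; plots with matplotlib 3.10.9).

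The groups, contrasts, tests, gene lists, alternatives and the rule for naming genes were chosen before the data were examined, except where stated otherwise. The rule named, per line, the 10 genes per direction with the largest log2 fold change among called genes with a mean of at least 5 CPM in that line whose 4 treated libraries all lay on 1 side of the 4 vehicle libraries. It named the 10 genes per direction with the largest mean change among genes called with the same sign in all 3 lines with at least 5 CPM in each. It also named the 4 genes with the largest difference per pair of lines (at least 5 CPM in both), up to 4 members with the smallest p of each described list (at least 1 CPM), and always the creatine genes and MECOM. Some genes that this rule names are not reported here.

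The alternatives were DESeq2 size factors and Wald tests (DESeq2 1.42.0), library totals alone, limma-voom, no filter, a stricter filter (1 CPM in 4 libraries), non-robust dispersions, each line or pair of lines fitted alone, the replicate number as a block, each library left out in turn, camera with an estimated inter-gene correlation, and for the baseline tests the sum of CKMT1A and CKMT1B and CPM on library totals. Transcript length and GC trends were also removed with offsets (lowess span 0.3), settings chosen after seeing the data, using the longest protein-coding transcript of GENCODE release 29, else the longest, which gave a length for 23912 of the symbols (92.9%). The fit was tested on simulated data with known changes in the same design: at 1.5-fold it called 73.1% of changed genes in TF-1, 67.2% in UT-7 and 76.1% in UCSD-AML1, and between 0.0348% and 0.0766% of unchanged genes in the lines and for their mean. It called 0% for the differences between lines, where all lines had the same simulated changes. Only 67 of 14588 genes were changed at 1.5-fold, and about as many at 1.2-fold and at 2-fold. Genes were drawn independently of each other and no length or GC trend was simulated, so these rates may not hold in the real data.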

Results

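The series compares cyclocreatine with vehicle in 3 acute myeloid leukemia cell lines that its design describes as driven by EVI1, the protein encoded by MECOM. TF-1 is an erythroleukemia line that needs a growth factor, UT-7 is a growth factor-dependent megakaryoblastic line, and UCSD-AML1 carries a rearrangement of chromosome 3 at MECOM. Cyclocreatine is a creatine analog that creatine kinases phosphorylate. Each line received 3 mM cyclocreatine or vehicle for 24 h, with 4 libraries per group and 24 libraries in all. Library totals ran from 12794998 to 21200662 counts, and 14588 genes were tested. Values are mean CPM (counts scaled by TMM to a common library size) ± SD with n = 4 unless stated, log2 fold changes carry their SE, and adjusted p-values of genes are from edgeR. The SE was derived from the edgeR F statistic, as the size of the log2 fold change over the square root of F. It is approximate and can be too small for large changes from few counts. The p-values measure only the spread between these samples, because the labels do not say whether the 4 libraries of a group came from separate cultures. Symbols are given as in the files, and positions are not used here because the files follow GRCh37 and the annotation at hand follows GRCh38.

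Treatment was the main difference among the libraries of each line. The first principal component separated all treated from all vehicle libraries and held 73.2% of the variance in TF-1, 84.5% in UT-7 and 81.7% in UCSD-AML1. In TF-1 a further component with 12.3% of the variance set cyclocreatine replicate 1 at -17.51, while the other 3 treated libraries lay between 6.305 and 7.432. That library also had the highest share of counts in cytosolic ribosomal protein genes, 10.05% against 8.311% to 8.361% in the other treated TF-1 libraries.

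At baseline the 3 lines differed in most genes of creatine handling. SLC6A8, the creatine transporter, stood at 520.7 ± 18.6 CPM in vehicle-treated TF-1, 31.88 ± 2.276 in UT-7 and 7.829 ± 2.78 in UCSD-AML1. CKB, brain-type creatine kinase, was abundant in all lines, at 989.9 ± 18.83, 620.1 ± 16.31 and 399.2 ± 27.01 CPM. GAMT, which makes creatine from guanidinoacetate, was highest in UCSD-AML1 at 49.18 ± 1.635 CPM, against 20.12 ± 1.607 in TF-1 and 1.937 in UT-7. GATM, the enzyme before it in creatine synthesis, stood at 17.17 ± 2.188 CPM in TF-1 and was near the floor in UT-7 (12 counts over the group) and UCSD-AML1 (9 counts). MECOM stood at 412.2 ± 14.71 CPM in UCSD-AML1, 13.03 ± 2.432 in TF-1 and 6.344 ± 0.7389 in UT-7. The mitochondrial kinases CKMT1A and CKMT1B, near-identical genes whose reads cannot be told apart with certainty, summed to 1.033 ± 0.4767 CPM in TF-1 (66 counts). They had 0 counts in UT-7 and UCSD-AML1, which sets no upper limit on their level, since reads that fit both genes may not have been counted. Exact permutation tests (both directions) of 4 against 4 libraries, which cannot give p below 0.0286, reached that p and an adjusted p of 0.0368 in 21 of 27 comparisons of a gene between lines. The passing comparisons include those of TF-1 with the other lines for CKMT1A and CKMT1B, whose 0 counts leave the difference in level uncertain. The exceptions were the 3 comparisons of CKMT2 (that of TF-1 with UCSD-AML1 passed without TF-1 vehicle replicate 4, adjusted p = 0.0368 in the exact test), the UT-7 comparison with UCSD-AML1 for GATM (p = 0.371 in the exact test), and those of CKMT1A and CKMT1B between UT-7 and UCSD-AML1. CKM, muscle-type creatine kinase, differed between TF-1 and UT-7 by 0.44 on the log2 scale, a difference that did not pass with library totals alone (0.36, adjusted p = 0.134 in the exact test). Without any 1 of the TF-1 vehicle libraries it did not pass either (adjusted p 0.0701 to 0.0734 in the exact test), nor did that of CKM between UT-7 and UCSD-AML1 (0.52) without UT-7 vehicle replicate 3 (0.0701) or without any 1 of the UCSD-AML1 vehicle libraries (0.0734 each). With 3 libraries against 4 the exact permutation test could still reach p = 0.0286. Without TF-1 vehicle replicate 1, CKB, SLC6A8, GATM, GAMT and MECOM still did so between TF-1 and UT-7. The p of CKM for that pair then went from 0.0286 to 0.0571 in the exact permutation test, although the difference grew to 0.48.

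Under cyclocreatine the creatine transporter and brain-type creatine kinase fell in every line. SLC6A8 fell 2.16-fold in TF-1, to 241 ± 27.48 CPM (log2 fold change -1.11 ± 0.11, adjusted p = 3.73e-08). It fell 2.88-fold in UT-7, to 11.08 ± 3.042 CPM (-1.53 ± 0.18, 6.49e-07), and 5.06-fold in UCSD-AML1, to 1.547 ± 0.371 CPM (-2.34 ± 0.33, 1.05e-05). CKB fell to 666.8 ± 79.85 CPM in TF-1 (-0.57 ± 0.05, adjusted p = 3.56e-10), 365.8 ± 17.72 in UT-7 (-0.76 ± 0.06, 1.94e-12) and 285.6 ± 5.793 in UCSD-AML1 (-0.48 ± 0.06, 3.63e-08). GAMT fell in TF-1, to 14.47 ± 2.172 CPM (-0.47 ± 0.09, adjusted p = 1.24e-05), and rose in UCSD-AML1, to 57.45 ± 3.288 CPM (0.22 ± 0.07, 0.00849), where removing the GC trend ended the call (0.10, adjusted p = 0.188). In UT-7 GAMT did not pass (1.937 to 2.115 CPM, adjusted p = 0.649). CKM passed only in UCSD-AML1, from 5.866 ± 0.5605 to 4.48 ± 0.7341 CPM (-0.39 ± 0.15, adjusted p = 0.0312), against adjusted p = 0.765 in TF-1 and 0.277 in UT-7. This call for CKM was lost with limma-voom (0.0526) and without UCSD-AML1 vehicle replicate 2 (0.117) or cyclocreatine replicate 1 (0.0841), 3 (0.108) or 4 (0.0637). GATM in TF-1 went from 17.17 to 14.27 ± 0.9241 CPM and did not pass (-0.27 ± 0.12, adjusted p = 0.0599), though it passed with limma-voom (0.0247) and with library totals alone (0.0155). MECOM fell in UT-7, to 3.777 ± 0.0938 CPM (-0.74 ± 0.23, adjusted p = 0.0105), and in UCSD-AML1, to 338.8 ± 3.299 CPM (-0.28 ± 0.08, 0.00862; 0.101 with DESeq2's Wald test). In TF-1 it went from 13.03 to 10.81 ± 3.768 CPM (adjusted p = 0.148), and passed without cyclocreatine replicate 2 (-0.47, 0.00084). The mitochondrial pair CKMT1A and CKMT1B fell below the expression filter and was not tested for treatment; in TF-1 it summed to 1.033 ± 0.4767 CPM with vehicle and 0.9795 ± 0.502 under cyclocreatine (65 counts).

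**Figure D1:**
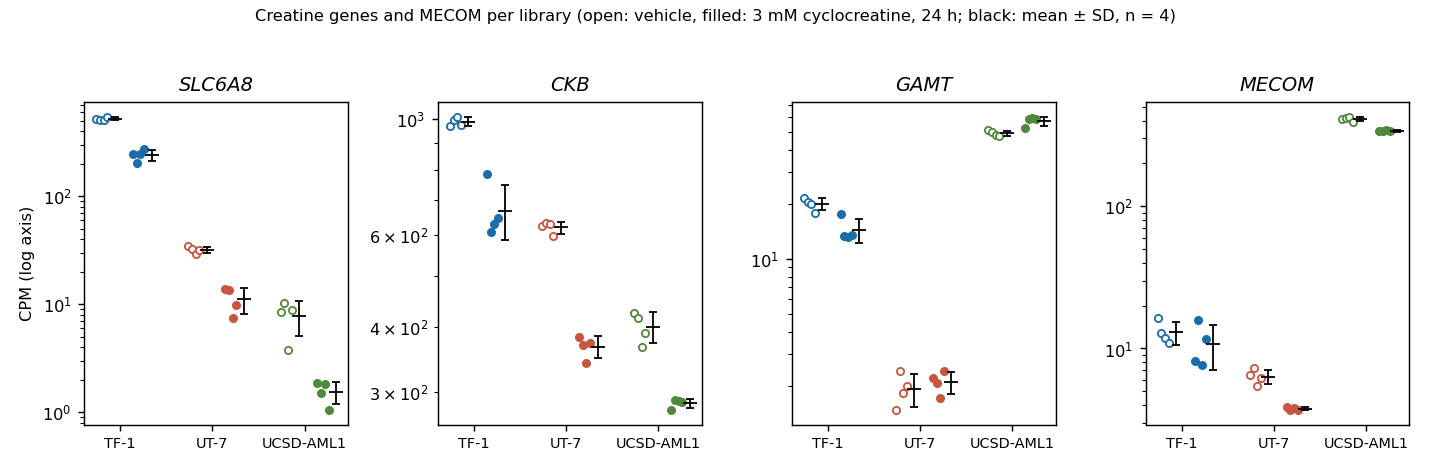
Points are CPM on a log axis for SLC6A8, CKB, GAMT and MECOM in each library of the 3 lines, with open points for vehicle, filled points for 3 mM cyclocreatine at 24 h, and black marks for the mean ± SD (n = 4). SLC6A8 went from 520.7 to 241 CPM in TF-1, 31.88 to 11.08 in UT-7 and 7.829 to 1.547 in UCSD-AML1.

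Among genes with a mean of at least 5 CPM in TF-1, the largest increase was in FAM132A. It rose 8.56-fold, from 1.099 ± 0.267 to 9.454 ± 1.837 CPM (log2 fold change 3.10 ± 0.20, n = 4 per group, edgeR). ENPP2, which encodes autotaxin, rose 3.94-fold to 26.75 CPM. SAT1, the polyamine acetyltransferase, rose 3.69-fold, from 46.71 ± 4.052 to 172.5 ± 18.39 CPM. The kinase SGK1 (3.61-fold), the aldo-keto reductase AKR1C2 (3.53-fold), FAM198B (3.38-fold) and LIPH (3.27-fold) followed. The guanylate-binding protein GBP2 (3.22-fold), SNORD25 (3.16-fold, a small nucleolar RNA inside a host gene, so that its reads are not certain to be its own) and DUSP15 (3.06-fold) completed the 10. The largest decreases at that level were in LTBP1, a latent TGF-beta binding protein (4.96-fold, 14.81 ± 2.522 to 3.005 ± 0.9967 CPM, log2 fold change -2.31 ± 0.15), and SLFN14 (4.91-fold). They included the kinases that start the main routes to choline and ethanolamine phospholipids. Choline kinase CHKA fell 4.47-fold, from 98.89 ± 3.462 to 22.13 ± 1.979 CPM (-2.16 ± 0.05). Ethanolamine kinase ETNK1 fell 4.35-fold, from 84.16 ± 4.405 to 19.26 ± 1.81 CPM. CELSR2 (4.45-fold), MMP15 (4.42-fold), ZNF345 (3.96-fold), IGFBP5 (3.92-fold), C1orf116 (3.83-fold) and SIGLEC6 (3.71-fold) also fell. The largest adjusted p of these 20 genes was 2.19e-09 (DUSP15). In all, 3901 genes rose and 4272 fell, 56.0% of those tested, 349 and 709 of them by at least 2-fold. The median size of a called change was 0.41 on the log2 scale. With library totals alone as the scaling the split was 3001 and 5225, and without cyclocreatine replicate 1 it was 3993 and 4326.

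All 73 measured cytosolic ribosomal protein genes rose in TF-1, with a median log2 fold change of 0.57 (camera adjusted p = 3.81e-43, and adjusted p = 0.183 with an estimated correlation), for example RPL13A (1.89-fold) and RPL14 (1.60-fold). Without cyclocreatine replicate 1, whose ribosomal protein share was the highest, 72 of the 73 rose. Of the 77 nuclear-encoded oxidative phosphorylation genes 55 rose, 2 fell and 20 did not pass, with UQCRB up 1.57-fold and NDUFB6 up 1.61-fold (camera adjusted p = 8.22e-08, and adjusted p = 0.479 with an estimated correlation). In the tricarboxylic acid cycle 16 genes rose, SUCLG2 by 1.47-fold, and 6 did not pass (camera adjusted p = 0.000266, and adjusted p = 0.183 with an estimated correlation). Arginine, proline and polyamine genes went both ways, with 11 higher, 5 lower and 6 not passing. SAT1 and ALDH18A1 (1.27-fold) rose while AZIN1 (1.96-fold) and OAT (1.46-fold) fell. That list's call (camera adjusted p = 0.0363, and adjusted p = 0.228 with an estimated correlation) was also lost with library totals alone (0.0536), with the length trend removed (0.144), and without vehicle replicate 1 (0.0534) or cyclocreatine replicate 1 (0.0814).

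Among JAK-STAT targets in TF-1 9 fell, 1 rose and 3 did not pass (camera adjusted p = 2.48e-07), and this call held with an estimated correlation (adjusted p = 0.0271). The kinases PIM1 (1.97-fold) and PIM2 (2.003-fold), the cytokine OSM (2.69-fold) and JUNB (1.86-fold) were lower. MAPK feedback and immediate early genes had 11 lower, 1 higher and 8 not passing, with CCND1 (2.46-fold), ETV4 (1.86-fold) and DUSP5 (1.65-fold) lower (camera adjusted p = 0.00217, and 0.0271 with an estimated correlation). The other TF-1 calls were all lost with an estimated correlation. Type I interferon genes had 16 lower, 0 higher and 6 not passing, with IFIT2 down 5.48-fold and IFIT3 2.08-fold (camera adjusted p = 0.0018, and adjusted p = 0.199 with an estimated correlation). In the amino acid and integrated stress response list 28 fell, 6 rose and 5 did not pass, with CBS (2.23-fold), WARS (1.84-fold) and TRIB3 (1.82-fold) lower (camera adjusted p = 5.28e-05, and adjusted p = 0.165 with an estimated correlation). Hypoxia genes had 15 lower, 0 higher and 7 not passing, EGLN1 and PDK1 among them at 1.47-fold and 1.46-fold lower (camera adjusted p = 0.000442, and adjusted p = 0.199 with an estimated correlation). Glycolysis genes had 11 lower, 4 higher and 8 not passing, with ENO2 (2.499-fold), PFKFB4 (2.46-fold) and the glucose transporter SLC2A3 (1.89-fold) lower (camera adjusted p = 0.00129, and adjusted p = 0.335 with an estimated correlation). Fatty acid synthesis and LXR targets had 8 lower, 2 higher and 4 not passing, with SREBF1 down 1.78-fold and FADS1 1.42-fold (camera adjusted p = 0.00995, and adjusted p = 0.183 with an estimated correlation).

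Megakaryocyte and erythroid markers were called lower in TF-1 with the preset correlation. Of 17 megakaryocyte markers 10 fell, among them SELP (3.43-fold), THBS1 (3.12-fold) and ITGB3 (2.42-fold), while ITGA2B rose 1.65-fold and 6 did not pass (camera adjusted p = 0.0351, and adjusted p = 0.199 with an estimated correlation). Of 25 erythroid markers 14 fell, including SLC4A1 (3.04-fold), TFRC (2.23-fold) and HEMGN (1.93-fold), 7 rose and 4 did not pass (camera adjusted p = 0.0363, and adjusted p = 0.279 with an estimated correlation). Both calls were lost without cyclocreatine replicate 2 (0.0582 each), and the erythroid call also without cyclocreatine replicate 4 (0.0523) and with TF-1 fitted alone (0.0532). The creatine pathway list had 3 lower and 2 not passing of 5 measured and was not called in the joint fit (camera adjusted p = 0.0539). It was called with TF-1 fitted alone (0.00612), with the length trend removed (0.00435), with the replicate block (0.0126), and without vehicle replicate 4 (0.0432) or cyclocreatine replicate 1 (0.00619). Adjusted over the list alone, the counts in TF-1 were the same except creatine pathway (4 lower), serine and one-carbon (7 higher), oxidative phosphorylation (56 higher) and tricarboxylic acid cycle (1 lower). They also differed for energy stress (5 higher), p53 (10 higher, 9 lower), erythroid (15 lower) and histones (2 lower). Without cyclocreatine replicate 1 the counts of higher and lower were 46 and 5 for oxidative phosphorylation, 2 and 13 for glycolysis. They were 4 and 16 for erythroid markers, and 6 and 25 for the amino acid list.

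Among genes with a mean of at least 5 CPM in UT-7, the transcription factor KLF2 rose most. It rose from near the floor, 0.3631 ± 0.0621 CPM, to 15.2 ± 1.166 CPM, 41.0-fold (log2 fold change 5.36 ± 0.19, n = 4 per group, edgeR). With 4 to 6 counts per vehicle library, this SE is likely too small. The orphan nuclear receptor NR4A2 rose 5.51-fold to 27.96 CPM and the complement receptor C5AR1 4.10-fold. The aldo-keto reductase AKR1C1 rose 3.61-fold, from 29.69 ± 1.131 to 107.2 ± 4.771 CPM. HIST2H2BE (3.38-fold), PTK7 (3.30-fold), DNHD1 (3.29-fold), the IgE receptor FCER2 (3.27-fold), TSPYL2 (3.21-fold) and SPP1, which encodes osteopontin (3.21-fold), completed the 10. The largest decrease at that level was in HEMGN, an erythroid nuclear protein, 4.24-fold from 22.56 ± 1.025 to 5.316 ± 0.5444 CPM (log2 fold change -2.08 ± 0.09). CD24 (3.72-fold), PTPRR (3.61-fold), FAM83A (3.52-fold), FAXDC2 (3.32-fold) and SLFN14 (3.26-fold) fell. So did CHKA (3.11-fold, 86.71 to 27.83 CPM), the water channel AQP1 (3.03-fold), FAM212B (3.00-fold) and the prostacyclin receptor PTGIR (2.99-fold). The largest adjusted p of these 20 was 1.03e-09 (PTPRR). In all, 3285 genes rose and 3404 fell, 45.9% of those tested, 323 and 273 of them by at least 2-fold, with a median size of 0.35 on the log2 scale.

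G1/S and G2/M genes went opposite ways in UT-7. Of 33 G1/S and DNA replication genes 29 fell, 0 rose and 4 did not pass, with the helicase subunits MCM3 (1.57-fold), MCM7 (1.53-fold) and MCM4 (1.44-fold) lower (camera adjusted p = 1.94e-14, and 0.000589 with an estimated correlation). Of 34 G2/M and mitosis genes 26 rose, 1 fell and 7 did not pass, with cyclin B1 gene CCNB1 (1.38-fold) and KIF2C (1.32-fold) higher (camera adjusted p = 2.92e-07, and 0.0367 with an estimated correlation). Cholesterol biosynthesis rose, with 16 higher, 3 lower and 6 not passing, MSMO1 by 2.03-fold and HMGCS1, which makes HMG-CoA, by 1.585-fold (camera adjusted p = 5.05e-08, and 0.0204 with an estimated correlation). JAK-STAT targets had 11 lower, 1 higher and 1 not passing, with SOCS3 (2.24-fold), PIM2 (2.08-fold) and CISH (1.68-fold) lower (camera adjusted p = 5.05e-08, and 0.0167 with an estimated correlation). Erythroid markers had 15 lower, 1 higher and 9 not passing, with the mitochondrial iron carrier SLC25A37 down 1.86-fold (camera adjusted p = 2.92e-07, and 0.0167 with an estimated correlation). Of 5 metallothionein and zinc response genes 3 rose and 2 did not pass, MT1X by 2.07-fold and MT2A by 1.995-fold (camera adjusted p = 0.00433, and 0.03 with an estimated correlation).

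The remaining UT-7 calls were lost with an estimated correlation. Cytosolic ribosomal protein genes had 71 higher and 2 not passing, with a median log2 fold change of 0.31 and RPL13A up 1.47-fold (camera adjusted p = 6.7e-18, and adjusted p = 0.306 with an estimated correlation). MYC and ribosome biogenesis genes went the other way, with 21 lower, 1 higher and 7 not passing, MYC down 1.60-fold and NOP58 1.35-fold (camera adjusted p = 6.05e-06, and adjusted p = 0.0773 with an estimated correlation). Energy stress, FOXO and MondoA targets had 7 higher, 5 lower and 3 not passing, with SESN3 (2.92-fold) and TXNIP (2.496-fold) higher (camera adjusted p = 0.00128, and adjusted p = 0.0952 with an estimated correlation). Glycolysis had 13 lower, 2 higher and 8 not passing, the lactate exporter SLC16A3 down 2.06-fold (camera adjusted p = 0.000546, and adjusted p = 0.306 with an estimated correlation). Hypoxia genes had 11 lower, 1 higher and 10 not passing, BNIP3 down 1.62-fold (camera adjusted p = 0.0084, and adjusted p = 0.306 with an estimated correlation). Megakaryocyte markers had 10 lower, 1 higher and 6 not passing, with PLEK (2.42-fold) and THBS1 (2.17-fold) lower (camera adjusted p = 0.00348, and adjusted p = 0.0773 with an estimated correlation). The endoplasmic reticulum unfolded protein response had 12 higher, 4 lower and 7 not passing, the chaperone gene HSPA5 up 1.37-fold (camera adjusted p = 0.00458, and adjusted p = 0.114 with an estimated correlation). NF-kB and inflammatory genes had 7 higher, 2 lower and 6 not passing, CXCL8 up 2.32-fold (camera adjusted p = 0.0163, and adjusted p = 0.207 with an estimated correlation). The creatine pathway had 2 lower (SLC6A8 and CKB) and 3 not passing (camera adjusted p = 0.0163, and adjusted p = 0.195 with an estimated correlation). Replication-dependent histones had 6 higher and 6 not passing, HIST1H2BK up 1.65-fold (camera adjusted p = 0.0165, 0.0648 with the length trend removed, and adjusted p = 0.295 with an estimated correlation). Oxidative phosphorylation had 24 higher, 3 lower and 50 not passing (camera adjusted p = 0.0294, and adjusted p = 0.776 with an estimated correlation). That call for oxidative phosphorylation was lost with library totals alone (0.0598), with the length trend removed (0.125), and without UT-7 vehicle replicate 4 (0.0623), cyclocreatine replicate 1 (0.0581) or cyclocreatine replicate 4 (0.0735). Adjusted over the list alone, the UT-7 counts were the same except arginine (9 higher), cholesterol (17 higher), glycolysis (14 lower), oxidative phosphorylation (22 higher), tricarboxylic acid cycle (11 higher), autophagy (2 lower) and p53 (10 higher). Further exceptions were BCL2 (3 higher, 6 lower), MYC (2 higher), unfolded protein response (13 higher), metallothioneins (4 higher), MAPK (5 higher), interferon (1 higher) and erythroid (17 lower).

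Among genes with a mean of at least 5 CPM in UCSD-AML1, the transcription factors KLF2 and JUN rose most. KLF2 rose 104-fold, from 0.4923 ± 0.1625 to 51.89 ± 4.045 CPM (log2 fold change 6.70 ± 0.15, n = 4 per group, edgeR). Its vehicle libraries held 4 to 10 counts each, so this SE is likely too small. JUN, an AP-1 subunit, rose 6.58-fold, from 1.841 ± 0.4621 to 12.34 ± 0.7841 CPM. The orphan nuclear receptor NR4A1 rose 4.74-fold, TSC22D3, the glucocorticoid-induced leucine zipper, 4.33-fold to 94.02 ± 4.044 CPM, and KLF6 4.04-fold to 78.17 CPM. Cytidine deaminase gene CDA (4.30-fold), MIR3648-1 (3.97-fold, a symbol whose sequence lies in ribosomal RNA repeats, with the largest adjusted p of the 20, 0.000199), ITGA10 (3.41-fold), mitochondrial arginase ARG2 (3.14-fold) and the Notch ligand JAG2 (3.12-fold) completed the 10. PFKFB2, a bifunctional regulator of glycolysis, fell 4.62-fold, from 33.73 ± 2.189 to 7.282 ± 0.5854 CPM (log2 fold change -2.21 ± 0.09). FGF23, a phosphate-regulating hormone, fell 3.13-fold, from 158.3 ± 3.847 to 50.58 ± 1.794 CPM, and P-selectin gene SELP 3.10-fold, from 207.5 ± 6.164 CPM. VSIG2 (4.27-fold), the chemokine receptor CCR6 (4.07-fold), RPH3A (3.97-fold), PRUNE2 (3.37-fold), DNAJC6 (3.11-fold), the platelet-activating factor receptor PTAFR (3.08-fold) and OLFM4 (3.01-fold) also fell. In all, 2790 genes rose and 3112 fell, 40.5% of those tested, 194 and 250 of them by at least 2-fold, with a median size of 0.31 on the log2 scale.

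Megakaryocyte markers fell in UCSD-AML1, with 10 lower, 3 higher and 4 not passing. The platelet receptor genes GP6 (2.93-fold) and GP1BA (2.57-fold) and the integrin ITGB3 (1.99-fold) were lower (camera adjusted p = 8.55e-14, and 0.000381 with an estimated correlation). MAPK feedback and immediate early genes had 8 lower, 2 higher and 10 not passing, with CCND1 (2.45-fold), DUSP5 (1.72-fold) and ETV5 (1.65-fold) lower although JUN was higher (camera adjusted p = 0.00447, and 0.0339 with an estimated correlation). The other UCSD-AML1 calls were lost with an estimated correlation. Cytosolic ribosomal protein genes had 70 higher and 3 not passing, with a median log2 fold change of 0.26 and RPL12 up 1.30-fold (camera adjusted p = 5.04e-16, and adjusted p = 0.426 with an estimated correlation). Type I interferon genes had 15 lower, 3 higher and 4 not passing, MX2 down 1.89-fold and RSAD2 1.73-fold (camera adjusted p = 1.38e-05, and adjusted p = 0.109 with an estimated correlation). The unfolded protein response list had 14 lower, 1 higher and 8 not passing, SDF2L1 down 1.73-fold and XBP1 1.496-fold (camera adjusted p = 0.0016, and adjusted p = 0.133 with an estimated correlation). JAK-STAT targets had 6 lower, 1 higher and 6 not passing, PIM2 down 2.54-fold (camera adjusted p = 0.00347, and adjusted p = 0.208 with an estimated correlation).

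Osmolyte transport had 5 higher, 1 lower and 2 not passing of 8 in UCSD-AML1. The betaine transporter SLC6A12 rose from 0.3096 to 2.724 CPM, the inositol transporter SLC5A3 2.30-fold and the taurine transporter SLC6A6 1.82-fold, while SLC38A1 fell 1.61-fold (camera adjusted p = 0.00358, and adjusted p = 0.208 with an estimated correlation). Energy stress, FOXO and MondoA targets had 6 higher, 5 lower and 4 not passing, TXNIP up 2.26-fold and CITED2 down 1.52-fold, with a median of -0.02 and a mean of 0.20 and a test pointing up (camera adjusted p = 0.00593, and adjusted p = 0.217 with an estimated correlation). Autophagy and lysosome genes had 12 higher, 1 lower and 9 not passing, FLCN up 1.62-fold (camera adjusted p = 0.0163, and adjusted p = 0.281 with an estimated correlation). Hypoxia genes had 13 lower and 9 not passing, BNIP3 down 1.83-fold (camera adjusted p = 0.0183, and adjusted p = 0.426 with an estimated correlation). Oxidative phosphorylation had 26 higher, 5 lower and 46 not passing (camera adjusted p = 0.0184, 0.358 with the length trend removed, and adjusted p = 0.794 with an estimated correlation). Arginine, proline and polyamine genes had 9 higher, 5 lower and 8 not passing (camera adjusted p = 0.0317, 0.0744 with the length trend removed, and adjusted p = 0.248 with an estimated correlation). The creatine pathway had 3 lower, 1 higher and 1 not passing (camera adjusted p = 0.0414, 0.0923 with UCSD-AML1 fitted alone, and adjusted p = 0.324 with an estimated correlation). Adjusted over the list alone, the UCSD-AML1 counts were the same except arginine (10 higher), cholesterol (10 higher), amino acid (11 lower), glycolysis (5 higher), oxidative phosphorylation (28 higher) and mitochondrial biogenesis (7 higher). Further exceptions here were autophagy (13 higher), G1/S (13 lower), MYC (3 higher), ribosomal proteins (73 higher), unfolded protein response (3 higher, 15 lower), MAPK (3 higher) and stromal markers (0 lower).

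**Figure D2:**
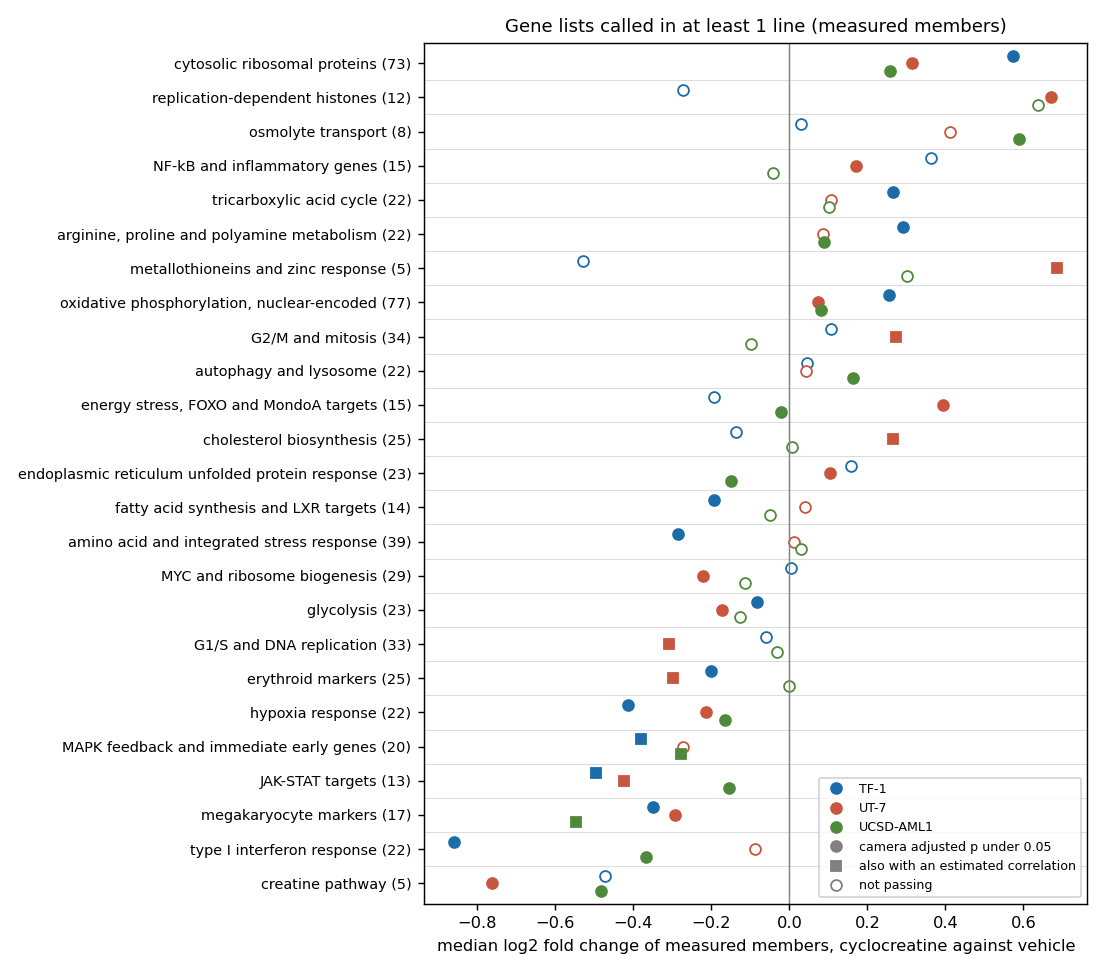
Points are the median log2 fold change (cyclocreatine against vehicle) of each gene list called in at least 1 line, with measured members in parentheses, colored by line; filled points passed camera at adjusted p under 0.05, squares also passed with an estimated correlation, and open points did not pass. Ribosomal protein medians lay at 0.57, 0.31 and 0.26 and stayed above 0 under each scaling tried.

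Among genes called in the same direction in all 3 lines, with at least 5 CPM in each, those with the largest mean changes were SAT1, ETNK1 and CHKA. SAT1 rose in every line, 2.80-fold on average (mean log2 fold change 1.49 ± 0.04), reaching 207.9 CPM in UT-7 and 104.4 in UCSD-AML1. TXNIP, which restrains glucose uptake, rose 2.14-fold (1.10 ± 0.02; 354 to 610.7 CPM in TF-1, 532.1 to 1328 in UT-7 and 271.7 to 615.2 in UCSD-AML1). The mitochondrial carrier UCP2 rose 2.09-fold. ETNK1 fell 3.18-fold (-1.67 ± 0.04) and CHKA 3.02-fold (-1.59 ± 0.03). The kinase PIM2 fell 2.20-fold (-1.14 ± 0.03). GBP2 (2.51-fold), DNHD1 (2.49-fold), RAPGEFL1 (2.46-fold), CUL7 (2.21-fold), NT5M (2.18-fold), RAD52 (2.14-fold) and ZNF467 (2.14-fold) also rose in all lines. MTURN (2.498-fold), HYAL3 (2.44-fold), HEMGN (2.40-fold), FYB (2.32-fold), PFKFB2 (2.27-fold) and PLEKHA6 (2.21-fold) also fell in all lines. The largest adjusted p of these for the mean change was 1.37e-14 (DNHD1). SLC6A8 (-1.66 ± 0.13, adjusted p = 6.07e-10), CKB (-0.61 ± 0.03, 3.7e-16) and MECOM (-0.43 ± 0.10, 0.000497) were lower on average as well.

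**Figure D3:**
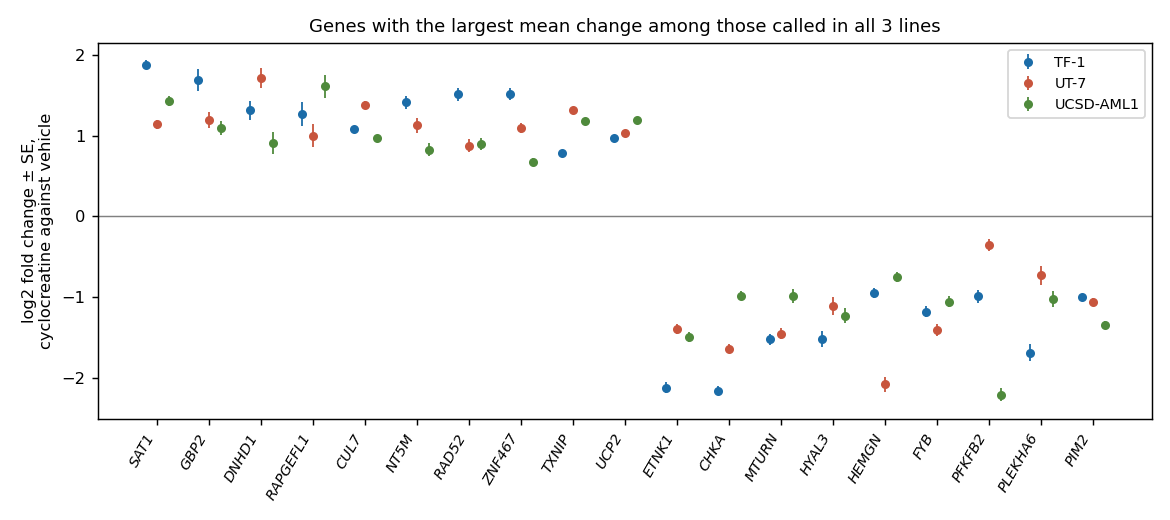
Points are the log2 fold change ± SE (cyclocreatine against vehicle, n = 4 per group) in each line for genes with the largest mean change among those called in the same direction in all 3 lines with at least 5 CPM in each. SAT1 lay at 1.88, 1.14 and 1.44 and ETNK1 at -2.12, -1.40 and -1.50 in TF-1, UT-7 and UCSD-AML1.

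The same direction was called in all 3 lines for 1278 higher genes, where independent calls would give 168, and for 1309 lower genes, against 213. Opposite calls were rarer than under independence: 421 against 1872 for TF-1 and UT-7, 443 against 1649 for TF-1 and UCSD-AML1, and 466 against 1352 for UT-7 and UCSD-AML1. The log2 fold changes correlated across genes with at least 5 CPM at Pearson's r of 0.688, 0.613 and 0.586 for the same pairs (Spearman's rho 0.662, 0.625 and 0.557), although genes are not independent replicates. The mean change was called for 4062 higher and 4288 lower genes, with JAK-STAT targets such as PIM1 and CISH at 11 lower, 0 higher and 2 not passing (camera adjusted p = 4.93e-08, and 0.0326 with an estimated correlation). MAPK feedback genes had 12 lower, 2 higher and 6 not passing for the mean (camera adjusted p = 0.00421, and 0.0326 with an estimated correlation). Of the mean calls lost with an estimated correlation, all 73 ribosomal protein genes were higher (camera adjusted p = 3.5e-39, and adjusted p = 0.212 with an estimated correlation). Megakaryocyte markers had 9 lower, 1 higher and 7 not passing (0.000478 with camera, and adjusted p = 0.0663 with an estimated correlation), and hypoxia genes 14 lower and 8 not passing (0.000385, and adjusted p = 0.212 with an estimated correlation). Oxidative phosphorylation had 50 higher, 6 lower and 21 not passing (camera adjusted p = 3.63e-05, and adjusted p = 0.535 with an estimated correlation). Glycolysis had 15 lower, 4 higher and 4 not passing (camera adjusted p = 0.000385, and adjusted p = 0.346 with an estimated correlation). Other mean calls were lost as well, with camera adjusted p 0.212 to 0.419 with an estimated correlation. The test pointed up for the tricarboxylic acid cycle (camera adjusted p = 0.00571), energy stress (0.0162) and osmolyte transport (0.0464). It pointed down for G1/S (0.00683), erythroid markers (0.00819), creatine pathway (0.00957), fatty acid (0.0165), MYC and interferon (0.0393 each).

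The lines also differed in their response, by tests of the difference between the log2 fold changes of 2 lines in the joint edgeR fit. TSC22D3 fell in TF-1 (-1.05) and rose in UCSD-AML1 (2.11), a difference of -3.16 ± 0.12. Spectrin gene SPTB fell in TF-1 (-0.79) and UT-7 (-0.51) and rose in UCSD-AML1 (1.57), differences of -2.36 ± 0.10 and -2.08. JUN rose in UCSD-AML1 more than in UT-7 (0.83, difference -1.89) and TF-1 (difference -2.76 ± 0.14). In TF-1 it did not pass (-0.04, adjusted p = 0.654). Its treated level in UCSD-AML1, 12.34 CPM, was below the vehicle levels of UT-7 (25.04) and TF-1 (22.74). Treated SPTB likewise stood at 12.23 CPM in UCSD-AML1, against 64.55 in TF-1 and 155.7 in UT-7. TSC22D3 was the other way round, at 94.02 CPM in treated UCSD-AML1 and 5.266 in treated TF-1. The pseudokinase PTK7 fell in TF-1 (-0.32) and rose in UT-7 (1.72, difference -2.04 ± 0.12), as did RHOB (-0.43 and 1.34, difference -1.77) and the cell cycle inhibitor CDKN1C (-0.27 and 1.44, difference -1.70). PPP2R5B fell in TF-1 (-1.60) with -0.15 in UT-7 (adjusted p = 0.383; difference -1.45 ± 0.20), KLF6 rose less in UT-7 (0.39) than in UCSD-AML1 (2.01, difference -1.62), and PFKFB2 fell less (-0.35 and -2.21, difference 1.85). MIR3648-1, with -0.40 in TF-1 (not passing), differed from UCSD-AML1 by -2.38 ± 0.46, the largest adjusted p of these genes (0.000594). Among creatine genes SLC6A8 fell less in TF-1 than in UCSD-AML1 (difference 1.23 ± 0.37, adjusted p = 0.0165; 1.09 and 0.0508 without UCSD-AML1 cyclocreatine replicate 4). Its other differences did not pass: TF-1 against UT-7 (0.42, adjusted p = 0.164) and UT-7 against UCSD-AML1 (0.81, 0.177; 0.0206 without UCSD-AML1 vehicle replicate 3). GAMT differed between TF-1 and UCSD-AML1 (-0.70 ± 0.11, adjusted p = 5.63e-06) and between TF-1 and UT-7 (-0.60, 0.0365; 0.0891 with limma-voom and 0.0734 with the pair of lines fitted alone). CKB fell more in UT-7 than in UCSD-AML1 (-0.28 ± 0.08, adjusted p = 0.00871), a difference of -0.06 with the GC trend removed (0.442).

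List tests of these differences compared the log2 fold change under cyclocreatine between lines, not the level. Higher or lower in a line refers here to that change. G1/S and DNA replication genes were lower in UT-7 relative to both other lines: 26 higher, 1 lower and 6 not passing for TF-1 minus UT-7 (camera adjusted p = 7.33e-21, and 4.41e-05 with an estimated correlation) and 23 lower and 10 not passing for UT-7 minus UCSD-AML1 (3.26e-21, and 4.58e-05 with an estimated correlation). G2/M genes were higher in UT-7 than in UCSD-AML1 (27 higher, 7 not passing, camera adjusted p = 1.98e-16, and 0.00142 with an estimated correlation). The change of cholesterol genes was higher in UT-7 than in TF-1 (16 of 25 passing in that direction, camera adjusted p = 7.45e-20, and 0.000342 with an estimated correlation) and than in UCSD-AML1 (14 of 25, with 1 the other way, 3.14e-08, and 0.018 with an estimated correlation). Amino acid and integrated stress response genes were lower in TF-1 than in UT-7 (19 lower, 1 higher, 19 not passing, camera adjusted p = 1.96e-08, and 0.0132 with an estimated correlation) and than in UCSD-AML1 (21 lower, 18 not passing, 1.05e-07, and 0.044 with an estimated correlation). Unfolded protein response genes were lower in UCSD-AML1 than in TF-1 and in UT-7 (13 of 23 passing each time, camera adjusted p = 1.9e-09 and 6.22e-13, and 0.00692 and 0.00071 with an estimated correlation). MYC and ribosome biogenesis genes (22 higher, 1 lower, 6 not passing) and metallothioneins (3 lower, 2 not passing) also differed for TF-1 minus UT-7 (camera adjusted p = 1.11e-11 and 0.000432, and 0.00982 for both with an estimated correlation). Ribosomal protein genes rose more in TF-1 than in UT-7 (64 passing, camera adjusted p = 6.43e-17, and adjusted p = 0.322 with an estimated correlation) and UCSD-AML1 (65 passing, 3.32e-21, and adjusted p = 0.243 with an estimated correlation). No other list difference passed with an estimated correlation. Several more were called with the preset correlation only. Among them was G2/M for TF-1 minus UT-7 (13 lower, 1 higher, camera adjusted p = 2.75e-05, and 0.0846 with an estimated correlation). Oxidative phosphorylation was another, for TF-1 minus UT-7 (29 higher, 3.22e-06 with camera) and TF-1 minus UCSD-AML1 (32 higher, 1.4e-05). With an estimated correlation these were 0.535 and 0.514. In total 4011 genes differed in their change between TF-1 and UT-7 (2089 higher, 1922 lower), 4242 between TF-1 and UCSD-AML1 (2156 higher, 2086 lower) and 3351 between UT-7 and UCSD-AML1 (1671 higher, 1680 lower). With library totals alone the first split became 1637 and 2312, the second 1329 and 2766 and the third 1365 and 2031.

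Several lists were not called by camera in any line, although single members changed. NRF2 targets had 8 higher and 6 lower of 17 in TF-1, 6 and 5 in UT-7 and 7 and 5 in UCSD-AML1 (adjusted p = 0.222, 0.223 and 0.0765, the last at 0.0277 with UCSD-AML1 fitted alone), with AKR1C1 up 2.46-fold in TF-1 and heme oxygenase gene HMOX1 up 3.18-fold in UT-7 and 2.57-fold in UCSD-AML1. Granulocyte and monocyte markers had 6 higher and 2 lower of 18, then 4 and 3 in both other lines (adjusted p = 0.086, 0.84 and 0.728), with the G-CSF receptor gene CSF3R up 3.15-fold, 2.57-fold and 1.45-fold. Stem and progenitor regulators had 5 higher and 7 lower of 18, 3 and 6, and 7 and 4 (0.75, 0.545 and 0.699), with RUNX1 down 1.40-fold, 1.43-fold and 1.42-fold. p53 targets had 9 higher and 8 lower of 25 in both TF-1 and UT-7 and 8 and 2 in UCSD-AML1 (0.67, 0.729 and 0.0982), with CCNG1 up 1.47-fold in TF-1 and UT-7. BCL2 family genes had 1 higher and 7 lower of 14, 2 and 5, and 3 and 5 (0.183, 0.479 and 0.671), with BBC3 up 1.70-fold in UCSD-AML1. Serine and one-carbon genes had 6 higher and 7 lower of 20, 4 and 9, and 4 and 5 (0.692, 0.63 and 0.914). Mitochondrial biogenesis and chaperone genes had 10 higher and 4 lower of 17, 3 and 5, and 6 and 3 (0.304, 0.5 and 0.584), with the polymerase gene POLG up 1.42-fold, 1.501-fold and 1.36-fold. Heat shock genes had 5 higher and 6 lower of 15, 4 and 4, and 3 and 2 (0.785, 0.825 and 0.546). Lymphoid markers had 1 higher and 2 lower of 12, 0 and 0, and 2 and 2 (0.935, 0.974 and 0.914), and stromal and epithelial markers 2 higher and 1 lower of 8, 0 and 0, and 0 and 1 (0.67, 0.926 and 0.99). None of the 15 mitochondrial-encoded transcripts was measured. In these lists the median, the mean and the test's direction differed in sign for NRF2 in TF-1 and UT-7, p53 in TF-1 and UT-7, serine and one-carbon in TF-1 and UCSD-AML1, heat shock in TF-1 and UCSD-AML1, BCL2, granulocyte and monocyte in UCSD-AML1, and lymphoid and stromal markers in all 3 lines.

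Lists called in 1 or 2 lines did not pass in the others in the joint fit of all libraries with TMM scaling. In TF-1 these were osmolyte transport (3 higher, 1 lower, adjusted p = 0.785 with camera), cholesterol (9 and 12, 0.143), energy stress (4 and 8, 0.494), autophagy (9 and 5, 0.433), G1/S (11 and 14, 0.784), G2/M (17 and 5, 0.206), MYC (12 and 7, 0.477), unfolded protein response (10 and 4, 0.051), metallothioneins (0 and 1, 0.734), NF-kB (6 and 2, 0.0631) and histones (1 and 3, 0.75). In UT-7 these were osmolyte transport (4 higher, 2 lower, 0.0606), arginine (8 and 6, 0.938), fatty acid (2 and 5, 0.141), amino acid (10 and 8, 0.807), tricarboxylic acid cycle (9 and 4, 0.219), autophagy (5 and 3, 0.5), MAPK (4 and 9, 0.0669) and interferon (2 and 2, 0.84). In UCSD-AML1 these were cholesterol (8 higher, 4 lower, 0.653), fatty acid (3 and 4, 0.466), amino acid (13 and 9, 0.344), glycolysis (4 and 11, 0.0715), tricarboxylic acid cycle (11 and 4, 0.072), G1/S (10 and 12, 0.914), G2/M (4 and 13, 0.0979), MYC (2 and 15, 0.0691), metallothioneins (1 and 0, 0.398), NF-kB (3 and 6, 0.653), erythroid markers (0 and 6, 0.0996) and histones (0 and 1, 0.546). Among these the median, the mean and the test's direction differed in sign for osmolyte transport, energy stress and G1/S in TF-1, fatty acid in UT-7, and G1/S in UCSD-AML1. Some of these passed under another setting. With library totals alone cholesterol (0.0489) and NF-kB (0.0489) passed in TF-1, and glycolysis and MYC (0.0478 each) in UCSD-AML1. With the line fitted alone osmolyte transport (0.00345) and MAPK (0.0381) passed in UT-7, and erythroid markers (0.0039) in UCSD-AML1. With the length trend removed osmolyte transport passed in UT-7 (0.0252), and glycolysis (0.0239), MYC (0.0239) and G2/M (0.0399) in UCSD-AML1. The unfolded protein response passed in TF-1 without vehicle replicate 2, 3 or 4 or cyclocreatine replicate 3 or 4 (0.0426 to 0.0453), and MAPK in UT-7 without vehicle replicate 1 (0.0496). In UCSD-AML1 glycolysis passed without vehicle replicate 3 (0.0219) or 4 (0.0465) or cyclocreatine replicate 4 (0.0441), the tricarboxylic acid cycle without vehicle replicate 3 (0.047), and MYC without vehicle replicate 4 (0.0335).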

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

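All tests on TF-1 cyclocreatine replicate 1 as a library, the KLF2 differences and the scaling test of the ribosomal protein genes were chosen after the result was seen, as were the removal of length and GC trends as settings and the TF-1 lists without that library; the other tests here were fixed before their results.

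Cytosolic ribosomal protein genes were higher in all 3 lines, with medians of 0.57, 0.31 and 0.26 on the log2 scale in TF-1, UT-7 and UCSD-AML1. Each median lay at percentile 100 of random lists matched on length and expression, whose medians were 0.24, 0.08 and 0.05, but the matching fell short in the direction of a length trend (median length 1181 against 1391, 1368 and 1438). It also fell short on expression, with median log2 CPM of 9.71 against 9.09 in TF-1, 9.3 against 8.65 in UT-7 and 9.51 against 8.71 in UCSD-AML1. A trend with abundance was therefore not fully controlled. With the transcript length trend removed, 72, 71 and 68 of the 73 cytosolic ribosomal proteins' genes still rose (medians 0.41, 0.28 and 0.18). That argues against this trend as the whole cause. The length used was that of the longest protein-coding transcript, so the removal may be too small where shorter transcripts of these genes prevail. Scaling is argued against as well, since a factor moves all genes of a library alike. The ribosomal protein median lay at least 0.145 above the central 95% of the matched medians in every line. The other translation genes whose transcripts start with a 5' TOP motif moved along: 22, 21 and 17 of 24 rose in the 3 lines, and their medians (0.48, 0.26 and 0.17) lay at percentile 99.98 or higher of matched lists, with EEF2 at 0.58, 0.42 and 0.28. Their matched genes were less abundant as well (median log2 CPM 9.44 against 8.94, 9 against 8.58 and 9.04 against 8.69). A shared change of 5' TOP transcripts may therefore be involved, as a hypothesis; reads shared with ribosomal protein pseudogenes were not tested and stay open, and with an estimated correlation the list itself did not pass (adjusted p = 0.183, 0.306 and 0.426).

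TF-1 cyclocreatine replicate 1 stood apart from the other 3 libraries of its group, with 10.05% of counts in ribosomal protein genes against 8.311% to 8.361% (gap over range 0.971), SAT1 at 199.9 CPM against 160.5 to 165.5 (0.873) and GAMT at 17.72 CPM against 13.21 to 13.53 (0.929). Lower depth is argued against, because its total of 17291832 counts (17.3 M) lies within the range of the others, 14993466 to 21200662. RNA from another of the lines is argued against, because 46 genes absent from the other TF-1 libraries and abundant in UCSD-AML1 gave a share of 0.0341%, and 7 such genes of UT-7 0.00462%. Its deviation from its group correlated across genes with transcript length at a Spearman's rho of -0.678, the largest size of the 24 libraries (next 0.509), and with GC content at 0.472, again the largest (next 0.416), so a difference in RNA quality or library preparation that acts by length, GC content or both may be involved. A difference of that culture stays open and untested, and without this library TF-1 had 3993 higher and 4326 lower genes.

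SLC6A8 was lower under cyclocreatine in all 3 lines. A GC trend between libraries is argued against, because with it removed at least 99.3% of the log2 change was left in each line and every call held. How reads that fit both SLC6A8 and its copy SLC6A10P were counted is not given in the sources used here. If they are in neither count, the fall lies in reads placed in SLC6A8 alone. The summed counts of both kept 100%, 101% and 100% of the log2 change in TF-1, UT-7 and UCSD-AML1. The copy's 182 counts over all libraries against 52022 for SLC6A8 are too few to move that sum, so reads shared with the copy stay open. A lower transcript level under the analog is a candidate explanation beside that, a hypothesis found and tested on the same data; whether uptake of cyclocreatine itself is needed cannot be read from this design.

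Further values lay far from the other 3 of their group: the gap to the nearest value, divided by the group's range, passed Dixon's limit, as chance does in about 1 in 20 groups. In all 22 of 284 gene values (7.75%) and 2 of 30 library measures did so. In TF-1 these were TXNIP in cyclocreatine replicate 2 (646.3 CPM against 597.9 to 600.2, gap over range 0.952), SPTB in vehicle replicate 1 (116.1 CPM, 0.833), CKM in vehicle replicate 3 (13.64 CPM, 0.85) and the TMM factor of vehicle replicate 1 (0.9921 against 0.9851 to 0.9857, 0.914). In UT-7 cyclocreatine replicate 3 these were AKR1C1 (100.1 CPM against 108.9 to 110.6, gap over range 0.833), FCER2 (51.69 against 56.02 to 56.76, 0.854), TXNIP (1187 against 1371 to 1380, 0.952) and PLEKHA6 (6.993 CPM, 0.897). In UT-7 they were also ETNK1 (107 CPM, 0.835) and PIM2 (187 CPM, 0.968) in vehicle replicate 3 and GATM in cyclocreatine replicate 2 (0.2313 CPM, 0.994). In UCSD-AML1 vehicle these were KLF2 in replicate 2 (0.2503 CPM against 0.5519 to 0.5983, gap over range 0.866) and CKM in replicate 2 (6.695 CPM, 0.841). In UCSD-AML1 cyclocreatine these were PFKFB2 (8.151 CPM, 0.849) and RAD52 (31.11 CPM, 0.918) in replicate 2, FGF23 (53.25 CPM, 0.863), DNAJC6 (8.143 CPM, 0.853) and PTAFR (5.752 CPM, 0.837) in replicate 3, and MTURN (8.383 CPM, 0.882), GAMT (52.52 CPM, 0.959) and GATM (0.1905 CPM with the others at 0, gap over range 1) in replicate 1.

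The response differed between lines, by tests of the difference itself in the joint fit. TF-1 and UT-7 differed in 4011 genes, with differences (TF-1 minus UT-7) of -2.04 for PTK7, -1.77 for RHOB, -1.70 for CDKN1C, -1.45 for PPP2R5B, -0.60 for GAMT (adjusted p = 0.0891 with limma-voom) and -4.70 for KLF2. List medians of that difference were -0.36 for cholesterol biosynthesis, -0.33 for the amino acid and integrated stress response, 0.35 for G1/S and DNA replication, 0.26 for MYC and ribosome biogenesis and -1.23 for metallothioneins. TF-1 and UCSD-AML1 differed in 4242 genes, with differences of -3.16 for TSC22D3, -2.76 for JUN, -2.38 for MIR3648-1, -2.36 for SPTB, 1.23 for SLC6A8 (adjusted p = 0.0508 without UCSD-AML1 cyclocreatine replicate 4), -0.70 for GAMT and -6.04 for KLF2, and list medians of -0.27 for the amino acid list and 0.28 for the unfolded protein response. UT-7 and UCSD-AML1 differed in 3351 genes, with differences of -2.08 for SPTB, -1.89 for JUN, 1.85 for PFKFB2, -1.62 for KLF6, -0.28 for CKB (-0.06 with the GC trend removed, adjusted p = 0.442) and -1.34 for KLF2. List medians of this last difference were 0.30 for cholesterol, -0.35 for G1/S, 0.33 for G2/M and 0.35 for the unfolded protein response.

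Chance as the source of the counts was tested by other splits of the libraries within lines. The real split gave the most called genes of 35 in TF-1 (8173, highest other 1080), UT-7 (6689, highest other 0) and UCSD-AML1 (5902, highest other 5), so that only 1 of 35 reached it. It gave the most of 100 for the mean effect (8350, highest other 3854) and for genes called in all 3 lines (2587, highest other 0). The share cannot fall below 1 of 35 or 1 of 100, so these results argue against chance without excluding it. Such splits also cannot tell the treatment from another difference between the treated and vehicle libraries of a line. For the differences between lines 4 of 100 splits reached 4011 for TF-1 and UT-7 (highest other 5566) and 2 of 100 reached 4242 for TF-1 and UCSD-AML1 (highest other 4600). For UT-7 and UCSD-AML1 1 of 100 reached 3351 (highest other 2097). These splits cannot decide whether the lines respond differently, because they remove the treatment effect instead of making it equal in both lines. The other splits that reached the real count kept the real groups of a line, so that line's treatment effect entered them, and among splits in which no line kept its real groups at most 1 gene was called.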

How the results depend on the processing

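Of 377 counts recomputed under the alternatives, 376 stayed within 1.5 times the reported value, and no called result reversed. For the differences between lines, only totals over both directions were among these counts. The genes higher for TF-1 minus UCSD-AML1, not among them, went from 2156 to 1329 with library totals alone, a change beyond 1.5 times. The exception among the 377 was the number of gene lists called in the lines, which went from 43 to 10 with an estimated inter-gene correlation. All 43 had their highest p there, and 8 were lost under another setting. Under the other settings the ranges were 3001 to 3927 higher and 3230 to 5225 lower genes in TF-1, 2811 to 3919 and 3287 to 3923 in UT-7, 2564 to 3633 and 2915 to 3680 in UCSD-AML1, and 1064 to 1450 and 1236 to 1568 in all 3 lines. They were 3425 to 4072 and 4192 to 4968 for the mean effect, and 3474 to 4199, 3728 to 4693 and 2982 to 4808 for the differences (TF-1 and UT-7, TF-1 and UCSD-AML1, UT-7 and UCSD-AML1). Leaving out each library gave 3704 to 3993 and 4058 to 4326 in TF-1, 2995 to 3130 and 3137 to 3203 in UT-7, 2494 to 2606 and 2751 to 2949 in UCSD-AML1, and 41 to 47 lists. Baseline tests passed in 19 of 24 with CKMT1A and CKMT1B summed, in 20 of 27 on library totals and in 20 to 21 without a library. Of the values of named genes 4357 of 4446 kept their call and direction (38 weaker, 34 stronger, 17 moved with no call), as did 4544 of 4794 list tests (120 weaker, 60 stronger, 70 moved) and 250 of 264 baseline tests, and 3 gene values could not be given under a setting. Length and GC trends, the lists with the length trend removed and the baseline tests without a library were chosen after seeing the data. The replicate numbers did not pair the libraries (correlations of same-numbered libraries -0.259 to 0.108, 1 of 12 over 0.1); with the replicate block the counts were 3287 lower in UT-7 and 2915 lower in UCSD-AML1, and the creatine pathway list passed in TF-1 (adjusted p = 0.0126), while osmolyte transport (0.0781) and MYC (0.0509) no longer passed for the mean. Depth limits the low genes: CKMT1A, CKMT1B, GATM outside TF-1 and vehicle KLF2 rest on few counts per library.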

Other observations

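The pathway test on phospholipid genes, the zinc finger test and the 5' TOP test were fixed before their results; the KLF2 values of TF-1 and the examples named here were chosen after their values were seen.

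Phospholipid synthesis genes other than CHKA and ETNK1 went both ways. Of 11 other measured genes, among them the ethanolamine kinase ETNK2, of the phosphatidylcholine and phosphatidylethanolamine routes 3 rose, 5 fell and 3 did not pass in TF-1 (median log2 fold change -0.33), 1 rose, 4 fell and 6 did not pass in UT-7 (-0.10), and 2 rose, 1 fell and 8 did not pass in UCSD-AML1 (-0.08). PCYT2, the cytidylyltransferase of the ethanolamine route, was lower in TF-1 (-0.47) and UT-7 (-0.61), while PEMT, which methylates phosphatidylethanolamine to phosphatidylcholine, was higher in all 3 lines (0.52, 0.36 and 0.36). KLF2 stood at 0.4224 CPM in vehicle-treated TF-1 and 0.6948 CPM under cyclocreatine (log2 fold change 0.66 ± 0.33, adjusted p = 0.0916), where UT-7 and UCSD-AML1 rose from similar levels to 15.2 and 51.89 CPM. The difference of TF-1 from UT-7 was -4.70 ± 0.48 (adjusted p = 1.68e-09 by edgeR), that from UCSD-AML1 -6.04 ± 0.49 (2.36e-12), and that between UT-7 and UCSD-AML1 -1.34 ± 0.42 (0.0168).

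Zinc finger genes (symbols beginning with ZNF) were lower in TF-1: of 483 measured, 191 fell, 67 rose and 225 did not pass, with a median log2 fold change of -0.21, and 39.5% fell against 29.3% of all genes.

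A candidate explanation for the fall of ETNK1 and CHKA is a lower expression of the whole phospholipid pathway. The other 11 genes pointed down in each line, with camera p-values of 0.261 in TF-1, 0.0116 in UT-7 and 0.539 in UCSD-AML1. The predicted fall with p under 0.05 in every line was therefore not met. Some of these genes rose in each line, so not all of the pathway fell. A test of 11 genes that does not pass cannot exclude a fall of part of it. In TF-1 PCYT1A (-0.46), PCYT1B (-0.67) and PCYT2 (-0.47) were among the genes that fell, while PEMT (0.52), PISD (0.33) and CHPT1 (0.13) rose. A candidate explanation for the lower zinc finger genes in TF-1 is the transcript length trend. Their median lay at percentile 0.01 of 10000 lists matched on length and expression, below nearly all of them, so length is argued against as the whole cause, and what lowers these genes stays open.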
